A study of Mus musculus with 2 samples.

How the data were processed

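Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to measure H3K9me3, trimethylation of histone H3 at lysine 9, in mouse hindbrain at embryonic day 16.5. Per the labels, the tissue came from the B6NCrl strain and was pooled over embryos of both sexes. The samples form 1 group of 2 biological replicates. Replicate 1 combined 2 technical replicates and its number of embryos is not given in the labels. Replicate 2 was 1 technical replicate from a pool of 37 embryos. The labels also say that the submitters had put the experiment's files under further review. The labels describe separate tissue pools under 1 donor identifier, and whether it marks the strain or shared animals is not given in the sources used here.

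The authors deposited 4 peak lists on the mm10 build. Per the notes deposited beside the lists, each replicate has its own list, a pooled list was made from the alignments of both replicates, and a list of replicated peaks was derived from the pooled list and both replicate lists. The aligner, the peak caller, their versions, the thresholds and the rule that makes a peak replicated are not given in the sources used here. The notes name further input files of each list without stating their role. In each list the authors deposited a signal value per peak, a unit whose reference level the notes leave unstated. They also deposited the −log10 of a p-value and the −log10 of a q-value per peak, per the notes' file format. These scores are the authors' own and were used to describe, rank and filter peaks, to compare peaks that overlap between the replicates, and to read back the depth behind each list. No reads were analysed here.

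Peaks on chromosomes 1 to 19 and X entered all tests of overlap, position and genes, while the shares of the deposited lists were taken over all sequences. Chromosome lengths of the reference (GRCm38.p6, the same primary sequence as mm10) were checked against the peak coordinates, and 0 peaks ran past a chromosome end. Genes came from the GENCODE vM21 annotation, with 53734 gene symbols on these chromosomes, of which 21727 were protein-coding. The soft-masked bases of the reference served as the repeat annotation. Coordinates are given counting from 1.

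Peaks are not independent replicates, so positions were tested by circular shift. All peaks of a list were moved together along each chromosome by a random distance, 1000 times with a fixed seed. This keeps the clustering of peaks and of genes. The p is two-sided, and 0.002 is the smallest that 1000 shifts can give. Such a p describes the placement of these lists on the genome and does not measure spread between animals. For gene lists, a member counted when a peak overlapped its gene body or the 2 kb upstream by at least 1 bp, and p-values were adjusted with the Benjamini-Hochberg method over 18 lists with at least 5 annotated members. A list passed at an adjusted p under 0.05. For genomic features, each peak was placed by its midpoint in a promoter (1 kb either side of a transcription start site), an exon, an intron or between genes, and p-values were adjusted over the 4 features. Shares carry 95% Wilson intervals, which cover counting error of peaks only. The 95% intervals of ratios also treat peaks as independent and do not measure spread between pools of embryos. Spearman's rho was taken across overlapping peaks, as a description with no p.

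The gene lists, the tests, the rule for named genes and most of the other settings were fixed before the data were examined. The rule takes, per list, up to 4 members with the highest signal value of a replicated peak in the gene body or 2 kb upstream. Ties were broken by covered bases and then by symbol. It also takes the 10 protein-coding genes with the most bases of replicated peaks, the 5 replicated peaks of highest signal value with their nearest gene, and the 5 windows of 1 Mb with the most bases. Gene symbols of the Gm and Rik kind were left out of the 10. Where gene models overlap they share peaks, and the peaks do not tell the genes apart.

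The depth behind the lists was read back from the paired signal and −log10 p that the authors deposited. The pairs were treated as a scaled fragment count plus 1 over a local background plus 1, with a Poisson tail above that background. Under this reading 100.0% of peaks in each of the replicate and pooled lists gave a whole number of fragments within 0.01. With p-values shuffled among 5000 peaks, 10.1% did so in replicate 1, 8.96% in replicate 2 and 8.6% in the pooled list. In 3 simulated lists with known counts, 100.0% of peaks were solved correctly. The sources used here do not state this formula, so the depths rest on this reading. A library size was then taken as the background divided by the shortest peak, which stands for the fragment length. The further inputs were assumed to be controls. Their relative size was read from the scale factor of the signal and from the steps between background levels.

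Each 31-mer of a replicated peak was looked up in the whole reference on both strands, and a peak with 5% or fewer repeated 31-mers was called largely unique. The gene list test was tested on simulated peaks first. With the 18482 replicated peaks moved by a random circular shift, 0 of 360 list tests in 20 simulations passed. The test itself uses such shifts, so this checks the computation and cannot show that the shifts suit real peaks. With peaks added to 94 zinc finger genes, 19 imprinted genes and 14 germline genes, each of these lists passed in 10 of 10 simulations.

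Alternatives covered the overlap rule, a −log10 q of 2 or more, the peaks of each replicate alone, the pooled list, the replicated peaks of highest signal, merged peaks, random placement, other gene windows, 10000 random gene lists matched on gene length, and members of a list within 500 kb counted as 1 locus. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks found in both replicates and largely unique peaks were added as settings after the data were examined. The test of local background was changed from a median to a mean before its result was seen, because the median sits at the lowest background level. The test of scaling was changed after its first result was seen. Peaks on chromosome Y and on sequences without a position on a chromosome were left out of the tests. Such sequences give the shifts no chromosome span, and chromosome Y was not among the chromosomes fixed for the tests.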

Results

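H3K9me3, a histone mark of repressed chromatin, was mapped by ChIP-seq in mouse hindbrain at embryonic day 16.5, in 1 group of 2 biological replicates. There was no other tissue, age or mark, so the comparisons are between the replicates, between the deposited peak lists, and between peak positions and their shifted positions. The list of replicate 1 held 73775 peaks and that of replicate 2 held 7986. The pooled list held 29225 peaks, and the list of replicated peaks held 18769. Replicated peaks had a median width of 283 bp and covered 6.66 Mb. The signal values are the authors' own scores and ran from 1.29 to 15.5 in that list. The pooled and replicated lists are single lists, so they carry no standard deviation between replicates. As read back from the authors' scores, the median summit held 10 fragments in replicate 1, 17 in replicate 2 and 23 in the pooled list. The genome background was 2.17 fragments in replicate 1, 2.48 in replicate 2 and 4.67 in the pooled list.

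Which gene families carried the mark was asked with the replicated peaks. Peaks lay in 157 of 470 C2H2 zinc finger genes, a family of DNA-binding proteins that sits largely in gene clusters, where the shifts gave a mean of 63.6. Clustered protocadherins, cell surface proteins of neurons, carried peaks in 53 of 57 members against 14.5. Imprinted genes, which are expressed from 1 parental copy, carried them in 41 of 47 against 8.98, and germline genes in 18 of 34 against 5.04. Vomeronasal receptors carried them in 75 of 327 members against 34.9, and antigen receptor segments in 58 of 620 against 8.14. These 6 of 18 lists passed the circular shift test, with adjusted p of 0.012 for zinc finger, imprinted and germline genes, 0.018 for protocadherins and 0.024 for vomeronasal receptors and antigen receptor segments.

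Zinc finger genes carried replicate 2 peaks in 118 members against 30.9 in the shifts, and replicate 1 peaks in 249 against 179. Imprinted genes carried replicate 2 peaks in 32 members against 4.68, and replicate 1 peaks in 41 against 21.98. Protocadherins carried replicate 2 peaks in 50 members against 5.71, and replicate 1 peaks in 53 against 33.3. All 6 lists passed with replicate 2 peaks alone. With replicate 1 peaks alone 5 of the 6 passed, and vomeronasal receptors did not at a permutation adjusted p of 0.0639. The folds over the shifts were lower there than with replicated peaks: 1.87 against 4.565 for imprinted genes, 1.44 against 3.57 for germline genes, 1.59 against 3.65 for protocadherins, 3.2 against 7.13 for antigen receptor segments and 1.39 against 2.47 for zinc finger genes. With replicated peaks at a −log10 q of 2 or more, germline genes, vomeronasal receptors and antigen receptor segments no longer passed, at folds of 3.32, 2.54 and 8.95 and permutation adjusted p of 0.0503 to 0.0539. With the 9221 replicated peaks of highest signal, vomeronasal receptors did not pass at a fold of 2.31. In gene bodies alone 36 antigen receptor segments carried a peak against 2.55, and against length-matched lists their fold was 2.73, with the call kept in both. Counted as loci, vomeronasal receptors carried peaks in 12 of 30 loci against 13.6 in the shifts, and antigen receptor segments in 1 of 5 against 2.72, so neither list passed. The protocadherins form 1 locus and could not be tested this way.

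**Figure D1:**
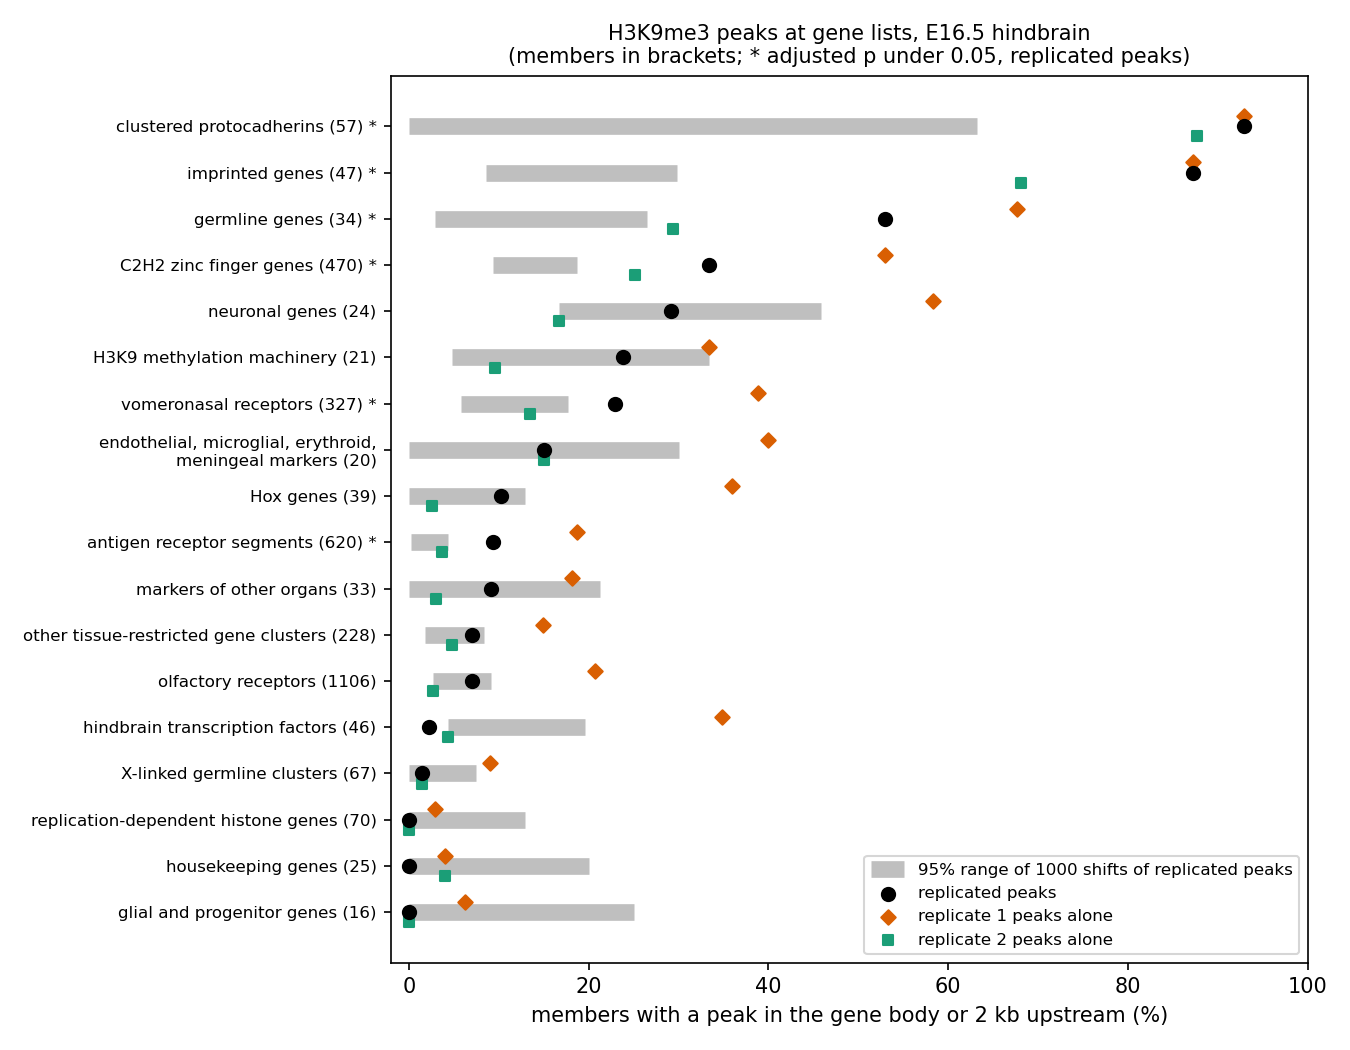
Share of the members of each gene list with an H3K9me3 peak in the gene body or 2 kb upstream (x axis, percent), for replicated peaks (black circles), replicate 1 peaks alone (orange diamonds) and replicate 2 peaks alone (green squares). Grey bars give the 95% range of 1000 circular shifts of the replicated peaks and apply to the black circles only. Protocadherins stand at 93.0% and imprinted genes at 87.2%, while housekeeping, histone and glial genes stand at 0 for replicated peaks and at 4%, 2.86% and 6.25% for replicate 1 peaks.

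Within 1 kb of a transcription start site, 51 of 57 protocadherins, 19 of 47 imprinted genes and 11 of 34 germline genes carried a replicated peak. The shifts gave means of 0.965, 0.99 and 0.428, each with an adjusted p of 0.012. Only 9 of 470 zinc finger genes did so, against 9.7 in the shifts (permutation adjusted p = 1). The zinc finger call thus held for gene bodies and not for start sites. Antigen receptor segments kept their fold at start sites (7.07 against 7.13, with 50 members) and vomeronasal receptors nearly so (2.02 against 2.15), but by the same permutation both missed the threshold there (adjusted p = 0.0647 and 0.468).

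The zinc finger genes of highest signal were Zfp180, Zfp981, Zfp606 and Zfp763. The Zfp180 peak spanned chromosome 7, 24103426 to 24107577, with its midpoint in a coding exon and a signal value of 9.23. The peaks of Zfp606 (chromosome 7, 12493125 to 12494370, signal 8.51) and Zfp763 (chromosome 17, 33017845 to 33019924, signal 8.47) were also centred in a coding exon. The Zfp981 peak was centred in an intron on chromosome 4, 146530323 to 146530866, with a signal of 9.22. All 4 peaks were overlapped by a peak of each replicate.

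Among the 47 listed imprinted genes the highest signal, 6.58, belonged to a peak on chromosome 6, 58906416 to 58907239. It was centred in the coding exon of Nap1l5, which lies within an intron of Herc3, and it spanned the annotated start of Nap1l5. The next was Plagl1, a zinc finger transcription factor, with a peak centred in a non-coding exon (chromosome 10, 13090272 to 13091300, signal 6.29). Commd1 followed, with a peak centred in an intron (chromosome 11, 22971780 to 22973084, signal 6.14). Germline genes were led by Meioc, a meiosis gene, at chromosome 11, 102665237 to 102666453, with a signal of 5.27. Ddx4, a germ cell RNA helicase, followed at chromosome 13, 112651663 to 112652676, with a signal of 5.13. Mael (chromosome 1, 166238119 to 166238908, signal 5.0) and Taf7l (chromosome X, 134475112 to 134476565, signal 4.69) completed the 4. These 4 germline peaks were centred in an intron of the gene model, and replicate 1 and replicate 2 peaks overlapped each of them. The Ddx4, Mael and Taf7l peaks also spanned the annotated start of their gene, while the Meioc peak lay downstream of its start.

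Vomeronasal receptors, the pheromone receptors, were led by Vmn1r181 with a signal of 5.71 upstream of the gene, then Vmn2r104 and Vmn2r17 at 5.56 and Vmn1r179 at 5.13. Antigen receptor segments were led by Ighv10-4 (6.44), Ighv1-26, Ighv1-25 and Ighv1-1, variable segments of the immunoglobulin heavy chain on chromosome 12. Ighv1-26 is annotated as a gene and the others as pseudogenes, and each peak lay upstream of its segment. Repeated 31-mers made up 6.27% in the Ighv10-4 peak, 12.4% in Ighv1-26, 9.27% in Ighv1-25 and 42.8% in Ighv1-1. All exceed the 5% limit for a largely unique peak. With largely unique peaks alone, the antigen receptor list had a fold of 3.52 over the shifts and an adjusted p of 0.0839.

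With Gm and Rik symbols left out, the 10 protein-coding genes with the most bases of replicated peaks were all protocadherins. Of those left out, Gm42416, Gm37013 and Gm37388 in the protocadherin window had at least as many bases as Pcdhga1. Pcdhga1 led with 83635 bases in 99 peaks, followed by Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2, Pcdhga5, Pcdhga6, Pcdhga7 and Pcdha1, the last with 46267 bases. The gamma models overlap and share most of these peaks, so the order among them follows gene length. Across the cluster and its flanks, chromosome 18, 36880184 to 37891873, there were 411 replicated peaks, of which replicate 1 peaks overlapped 387 and replicate 2 peaks overlapped 262.

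**Figure D2:**
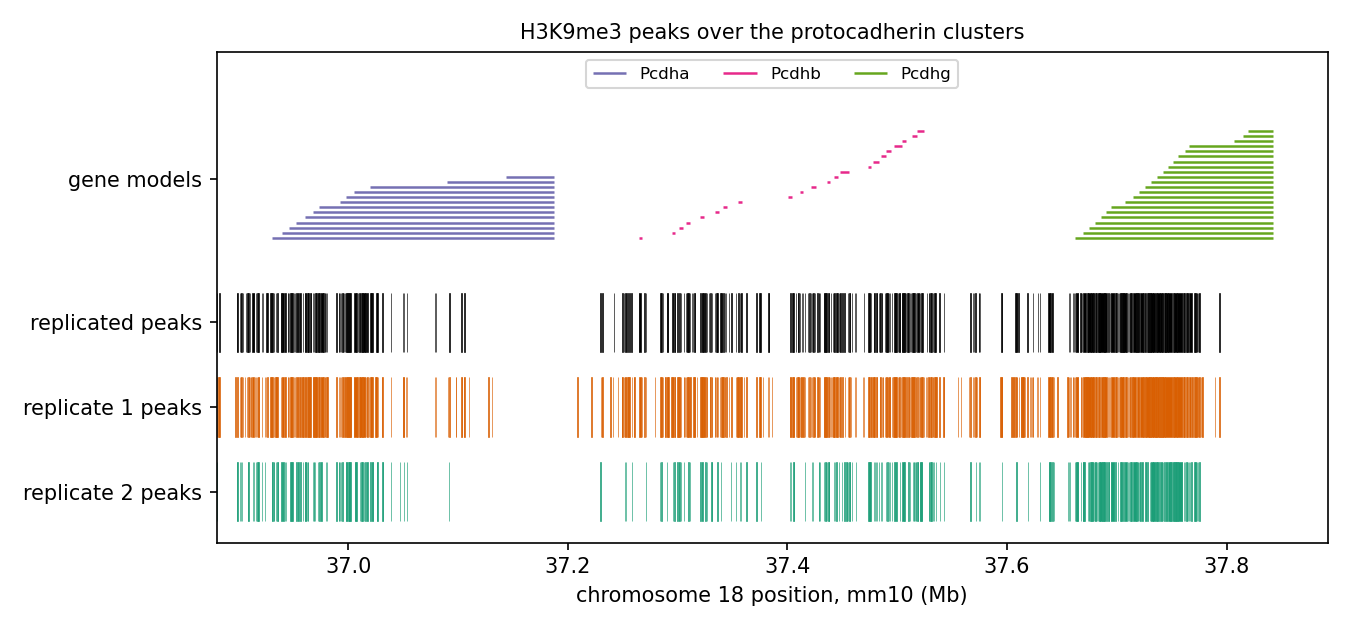
Map of the protocadherin clusters on chromosome 18 of mm10 (x axis, Mb), with gene models as coloured lines and each peak as a bar in black (replicated), orange (replicate 1) or green (replicate 2). Peaks of both replicates lie over the beta genes and over the 5′ part of the alpha and gamma clusters, with 541 replicate 1 peaks and 321 replicate 2 peaks in the region.

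The window of 1 Mb with the most bases of replicated peaks, 18.5% of its length, was this protocadherin window on chromosome 18, from 37000001 to 38000000. On chromosome 7, the window from 17000001 to 18000000 (8.03%) held Ceacam and Psg genes of placental and cell adhesion proteins. Also on chromosome 7, the window from 12000001 to 13000000 (7.25%) held 12 vomeronasal receptors and 9 zinc finger genes. The window from 33000001 to 34000000 (7.09%) held Scgb secretoglobin genes, and that on chromosome 12 from 114000001 to 115000000 (6.78%) held 88 antigen receptor segments.

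The replicated peak of highest signal value, 15.5, spanned chromosome 6, 30955626 to 30959297. It was 3672 bp wide and centred in the 3′ UTR of Klf14, an imprinted transcription factor gene outside the fixed lists. The next peak, signal 12.4, spanned chromosome 2 from 180642475 to 180643979. It was centred 519 bp upstream of Tcfl5, a testis transcription factor. At 1505 bp wide, it also spanned the annotated start of Tcfl5. A peak centred in a coding exon of Gm21887 on chromosome X, 170018441 to 170018974, had a signal of 10.9. Of its 31-mers, 100% were repeated elsewhere. The peak at chromosome 18, 37742575 to 37743764, signal 10.8, was centred in a coding exon of Pcdhgb6. The last, at chromosome 12, 47833812 to 47834204, signal 10.7, was centred 20759 bp downstream of the pseudogene Gm7392. Peaks of both replicates overlapped all 5.

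None of the other 12 lists passed. Glial and progenitor genes (0 of 16), housekeeping genes (0 of 25) and replication-dependent histone genes (0 of 70) had no replicated peak, against 1.45, 1.93 and 1.68 in the shifts. Hindbrain transcription factors had 1 of 46 against 5.03 (permutation adjusted p = 0.0719), the one being Rora, a nuclear receptor of Purkinje cells, with an intronic peak of signal 3.65. Neuronal genes had 7 of 24 against 7.63, with Grid2 (signal 5.71), Nefm (5.27), Nrxn1 (4.9) and Syt1 (4.83) highest. With replicate 1 peaks alone, housekeeping genes (1 of 25 against 6.58) and glial and progenitor genes (1 of 16 against 4.91) fell below the shifts, each at an adjusted p of 0.0216. In the same setting hindbrain transcription factors had 16 of 46 against 13.8 and neuronal genes 14 of 24 against 14.6. With replicate 2 peaks alone housekeeping genes had 1 of 25 against 0.859.

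Olfactory receptors carried replicated peaks in 77 of 1106 members against 55.9 (permutation adjusted p = 0.451), led by Olfr862, Olfr161, Olfr211 and Olfr853 with signals of 4.69 to 5.13. Against random lists matched on gene length alone, which do not keep the clustering of genes, the olfactory list passed at an adjusted p of 0.00154. Hox genes had 4 of 39 members with a peak against 1.57 (Hoxa11, Hoxd10, Hoxb7 and Hoxa3), and the highest signal was 3.67. X-linked germline clusters had 1 of 67 against 1.77, namely Rhox13. Other tissue-restricted clusters had 16 of 228 against 10.3, with Skint2, Skint5, Skint6 and Skint9 highest. The H3K9 methylation machinery had 5 of 21 against 3.77, and its 4 highest were Fam208a (signal 5.02, upstream of the gene), Atf7ip, Kdm4c and Suv39h1. Endothelial, microglial, erythroid and meningeal markers had 3 of 20 against 2.82 (Pdgfrb, Pecam1 and Tek), and markers of other organs had 3 of 33 against 3.2 (Cyp3a11, Nphs1 and Lgr5). None of the 4 Hox peaks was overlapped by peaks of both replicates, and the Hoxa3, Suv39h1 and Lgr5 peaks were overlapped by neither.

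Chromosome 7 had the highest density of replicated peaks, 7100 bp per Mb, which was 2.82 times the genome value of 2517 bp per Mb. The same ratio was 2.09 with replicate 1 peaks and 2.62 with replicate 2 peaks. Chromosomes 17 and 18 followed with ratios of 1.88 and 1.64. These were 1.55 and 1.22 with replicate 1 peaks, and 2.05 and 2.3 with replicate 2 peaks. On chromosome 18, 223345 bases of replicated peaks lay in the protocadherin cluster and its flanks. Chromosome X had the lowest ratio, 0.312, with 0.404 in replicate 1 and 0.431 in replicate 2. The pools held embryos of both sexes, and the densities were not corrected for the number of copies of chromosome X. With 1 group, no test was made of these densities.

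**Figure D3:**
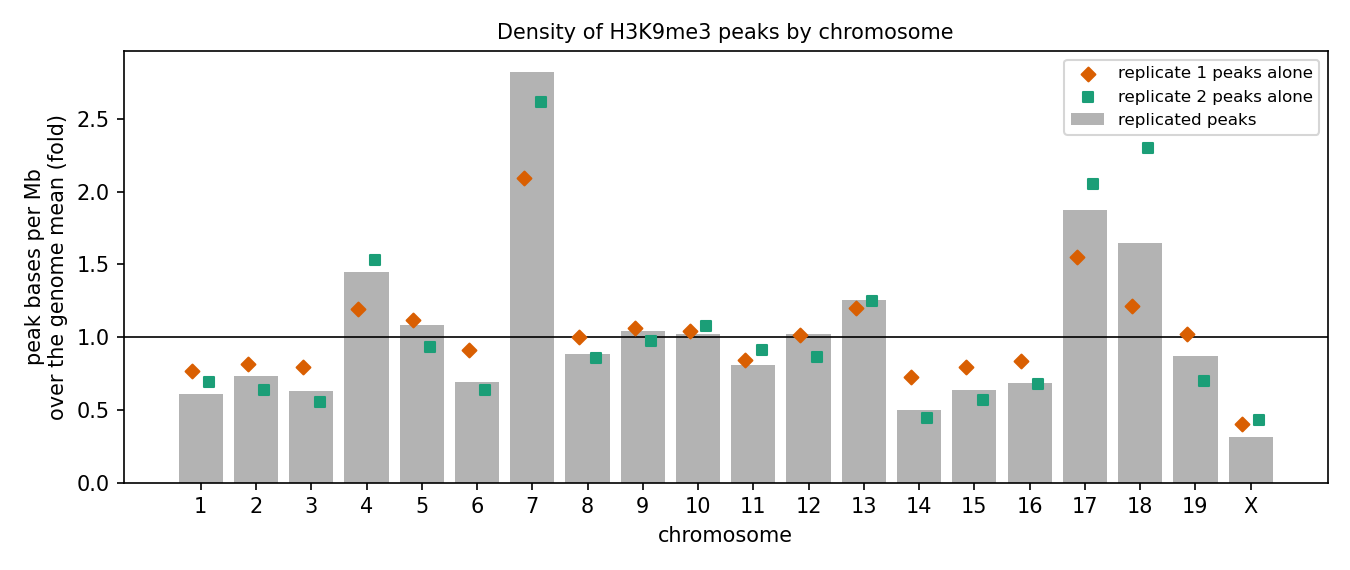
Bases covered by H3K9me3 peaks per Mb of each chromosome, divided by the value over all chromosomes shown (y axis, fold; line at 1). Bars give replicated peaks, orange diamonds replicate 1 peaks alone and green squares replicate 2 peaks alone. Chromosome 7 is highest among the bars at 2.82 and chromosome X lowest at 0.312.

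By genomic feature, 7.26% of the 18482 replicated peaks had their midpoint in an exon, where the shifts gave 4.25%. Promoters held 6.59% against 4.17%, and introns held 31.9% against 41.6%. Each of these differed from the shifts at an adjusted p of 0.00266, in replicated peaks and in replicate 2 peaks alone. The exon share was 11.5% with replicate 2 peaks. With replicate 1 peaks the exon share was 4.78% and the promoter share 4.86%, at an adjusted p of 0.002. Between genes lay 54.2% against 50% (permutation adjusted p = 0.00599), but with replicate 2 peaks alone that share was 48.9% against 50.3% (adjusted p = 0.529), and at a −log10 q of 2 or more it was 49.8%.

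Of the bases in replicated peaks, 24.6% were soft-masked as repeats, against 33.8% in the shifts (permutation p = 0.002, the smallest the shifts can give). The share was 27.5% in replicate 1 peaks and 21.8% in replicate 2 peaks, both below their shifts at the same p. How the authors treated reads that map to several places is not given in the sources used here, and repeats are where such reads fall.

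The replicates shared peak positions far beyond the shifts. On chromosomes 1 to 19 and X, 79.4% of replicate 2 peaks (6119 of 7704; 95% Wilson interval 78.5 to 80.3) overlapped a replicate 1 peak, against 1.77% in the shifts (permutation p = 0.002). In the other direction 7.87% of replicate 1 peaks overlapped a replicate 2 peak. With a reciprocal overlap of 50% the shares were 38.0% of replicate 2 peaks and 3.99% of replicate 1 peaks. When replicate 1 was limited to its 7704 peaks of highest −log10 p, 38.5% of replicate 2 peaks overlapped one of them. Of the 7336 replicate 1 peaks with the highest signal values, 30.3% overlapped a replicate 2 peak, and of the 7336 with the lowest 3.53% did. Across 6119 overlapping peaks, which are not independent replicates, Spearman's rho of the signal values was 0.229.

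The list of replicated peaks was a subset of the pooled list, since all 18769 had the coordinates of a pooled peak. Replicate 1 peaks overlapped 91.7% of them and replicate 2 peaks 33.8%. A peak of each replicate overlapped 30.4% (95% Wilson interval 29.7 to 31.03), and no peak of either overlapped 906. The share with a peak of each was 18.5% with a reciprocal overlap of 50% and 7.92% at a −log10 q of 2 or more, where replicate 2 kept 693 peaks for 7124 replicated peaks and so limited the share. With at least 50% of either peak required, 5602 pooled peaks were matched in both replicates, and all 5602 were in the replicated list. The remaining 13167 replicated peaks did not meet that rule.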

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

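The tests of library depth, of scaling, of repeated sequence in antigen receptor segments and of chance peaks were chosen after their results, or values close to them, had been seen. Signal appeared on sequences that entered none of the tests of position, replicate overlap and genes. Of the replicated peaks, 281 lay on sequences without a position on a chromosome and 6 lay on chromosome Y. Some of these sequences are assigned to a chromosome but not located on it. They are given here because peaks were listed where no test was made.

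The replicate 1 list was 9.24 times as long as the replicate 2 list. A shallower ChIP library in replicate 2 is argued against, since its library size was 1.21 times that of replicate 1. Weaker enrichment is argued against for the strongest peaks only. Over the 500 pooled peaks of highest fold over local background, replicate 2's fold over genome background was 1.08 times replicate 1's in the median. The 95% bootstrap interval of this median ran from 1.05 to 1.12, over 480 peaks found in both. These peaks were chosen in the pool, to which replicate 2 gave the larger library, and that favours its fold. For weaker peaks the question stays open: at or above a fold of 5.24 over genome background, replicate 1 had 24350 peaks and replicate 2 had 7925. Under the reading used here, replicate 2 needed a fold of 4.43 at the genome background and replicate 1 a fold of 2.76. Whether scaling of replicate 2 to a smaller control accounts for the difference in peak number stays open. That control was 0.465 times the size of replicate 1's, if the unnamed inputs are controls, as assumed here. The ratio of peak numbers was 1.51 at or above replicate 2's median fold, and its 95% interval of 1.46 to 1.57 straddles the limit of 1.5. This interval and the bootstrap interval treat peaks as independent. The ratio fell from 3.07 at replicate 2's 5th percentile and 1.61 at its 25th to 0.873 at its 75th. An earlier form of this test, replaced after its result was seen, set replicate 1 peaks of at least 3.47 times their local background against all 7986 replicate 2 peaks and gave 7.74, which decides nothing, since replicate 2 needed a fold of 4.43 at the genome background.

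For the excess at 6 gene families, reads shared between near-identical copies are argued against for zinc finger genes, whose fold was 2.51 with largely unique peaks alone and 2.47 with all; protocadherins (3.98), imprinted genes (5.18), germline genes (4.23) and vomeronasal receptors (2.23) also kept their call there. For antigen receptor segments the same restriction took the fold from 7.13 to 3.52 and ended the call with 12707 of 18482 peaks left, so a contribution of shared reads stays open. A local excess of reads in the control stays open too: the mean local background of the 1459 replicated peaks in these families was 0.982 times that of the others (95% interval 0.957 to 1.007), and 43.7% of them against 41.4% of the others lay above the genome background. This is below the limit of 1.5 written before, but it decides nothing, because the background was measured only at peaks that had exceeded it. No biological explanation was tested, since the design has 1 group.

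Replicated peaks that no replicate 2 peak overlaps numbered 12335 on chromosomes 1 to 19 and X. Chance peaks of replicate 1 are argued against as the whole account, since zinc finger genes had a fold of 2.53 over the shifts in these peaks alone (permutation adjusted p = 0.012). The list had already passed in the 18482 replicated peaks that include them, so this is not independent support. As part of the pooled list, these peaks also rest on reads of replicate 2. Which of them would be found again in a further pool of embryos stays open.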

How the results depend on the processing

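The settings with peaks found in both replicates and with largely unique peaks were added after the data were examined. Of 132 values that answer a comparison under another setting, 107 kept their call, 9 fell short of the threshold, 10 moved and 6 turned direction. A tested value kept its call when its direction and its side of the threshold held, whatever its size. A value without a test did so within 1 standard deviation between replicates or its 95% interval, and a number of lists within 1.5 times. Among kept calls, the protocadherin fold of 3.65 was 52.9 at start sites and 1.59 with replicate 1 alone, that of imprinted genes was 1.87 with replicate 1 alone, that of antigen receptor segments was 14.1 in gene bodies and 2.73 against length-matched lists, that of vomeronasal receptors was 3.24 against length-matched lists, and the overlap of replicate 2 was 38.0% with reciprocal overlap, 38.5% with replicate 1 held to as many peaks and 91.0% at the q limit in both lists. The overlap of replicate 1, 7.87%, was 3.99%, 32.1% and 1.85% in these settings. In peaks found in both replicates the fold was 10.9 for protocadherins, 8.43 for imprinted genes, 5.44 for germline genes and 4.28 for zinc finger genes. At a −log10 q of 2 or more it was 8.6 for protocadherins and 4.15 for zinc finger genes. The share of peaks between genes, 54.2%, ran from 48.9% to 57.03% over the separate replicates, and was 49.8% at a −log10 q of 2 or more, 48.6% in peaks found in both replicates and 52.6% in the peaks of highest signal. The zinc finger fold was 0.927 at start sites. Vomeronasal receptors had a fold of 1.29 to 2.54 over the separate replicates, 2.54 at the q limit, 2.31 in the peaks of highest signal, 2.02 at start sites and 0.881 by locus. Germline genes had 3.32 at the q limit. Antigen receptor segments had 8.95 at the q limit, 7.07 at start sites, 3.52 with largely unique peaks and 0.367 by locus. The number of lists that passed went from 6 to 3 at the q limit, 3 at start sites and 3 by locus. Counting by locus gave no value for protocadherins (1 locus) and Hox genes (4 loci). Spearman's rho rose from 0.229 to 0.295 with −log10 p and 0.297 with reciprocal overlap of 50%. The share of replicated peaks with a peak of each replicate fell from 30.4% to 18.5% with reciprocal overlap and 7.92% at the q limit, where the share was limited by the 693 replicate 2 peaks left. The ratio of chromosome 7 was 2.09 to 2.62 and that of chromosome X 0.404 to 0.431 over the separate replicates. Among lists that did not pass, 100 of 131 values kept their direction and stayed short of the threshold, 3 went past it and 28 crossed a fold of 1. Those 100 include Hox genes, 2.54 and 10.7 at start sites, and the H3K9 methylation machinery, 1.32 and 6.35 there. Over the separate replicates the lists that crossed were housekeeping genes (0.152 to 1.16), hindbrain transcription factors (0.786 to 1.16), endothelial, microglial, erythroid and meningeal markers (0.953 to 2.41), other tissue-restricted clusters (0.9991 to 2.24) and the H3K9 methylation machinery (0.636 to 1.13). Endothelial and related markers also stood at 0.757 in the pooled list and at 0 at the q limit, in the peaks of highest signal and at start sites. Markers of other organs stood at 1.36 in the pooled list, 1.15 with largely unique peaks, 1.015 in gene bodies, 1.98 at start sites and 1.1 against length-matched lists. X-linked germline clusters stood at 1.92 at the q limit, 1.24 in the peaks of highest signal, 1.67 in peaks of both replicates and 3.41 at start sites. Hox genes stood at 0 at the q limit and in peaks of both replicates, and at 0.762 in gene bodies. Neuronal genes stood at 1.11 in the peaks of highest signal, 1.04 in peaks of both replicates, 1.04 with largely unique peaks and 1.11 against length-matched lists. Other tissue-restricted clusters stood at 0.944 at start sites and 0.97 by locus, and olfactory receptors at 0.972 by locus. Among the 58 named genes, 8 had no replicate 2 peak, 1 had no replicate 1 peak and 10 had no replicated peak at the q limit. The cause of these changes was not tested.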

Other observations

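The test of the last exon was written before its result was seen. The comparison of G and C content was not among the tests fixed beforehand. Within zinc finger genes of more than 1 exon, 207 of 614 replicated peak midpoints (33.7%) lay in the last exon, which holds the zinc finger coding sequence in many of these genes, against 11.7% in the shifts (permutation p = 0.002). The share was 2.88 times the mean of the shifts, which is consistent with a placement over the last exon. In other protein-coding genes 407 of 7515 midpoints (5.42%) lay in the last exon against 3.55%, a fold of 1.53 (permutation p = 0.002). Both sets of genes thus exceeded their shifts. In both sets a midpoint was counted in each gene it lay in. Overlapping models, such as those of the gamma protocadherins, therefore count the same peak repeatedly, in the data and in the shifts. The difference between the folds of 2.88 and 1.53 was not tested. The last exon takes a median of 16.3% of the length of a zinc finger gene and 5.63% of that of other genes, which the shifts take into account.

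Replicated peaks were richer in G and C than their shifts, with 47.2% of bases against 41.9% (permutation p = 0.002). Replicate 1 peaks stood at 46.2% and replicate 2 peaks at 48.5%.

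Tcfl5 and Klf14, beside the replicated peaks of highest signal, belong to none of the fixed lists. Of the 58 named genes, 50 carried a replicate 2 peak and 57 a replicate 1 peak in the gene body or 2 kb upstream. The replicated peak of highest signal itself was overlapped by a replicate 1 peak in 54 genes, by a replicate 2 peak in 44 and by both in 43.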
